A study of Homo sapiens with 5 samples.

How the data were processed

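Single cells of human term placenta were measured, labelled as chorionic cells and sorted as positive for a CDX2-mCherry reporter, in 2 libraries of freshly isolated cells (replicates 1 and 4) and 3 libraries of cells expanded to passage 3 (replicates 2, 3 and 5). Per the labels' protocols, cells were thawed and run on the 10x Chromium Next GEM 3′ assay, aiming at about 3000 cells per library. The deposited values are UMI counts per gene and cell barcode, made with Cell Ranger 7.0.1 per the file headers, and not normalised. The submitters' processing notes list a mouse genome build, but every feature in the files is a human Ensembl gene with a human symbol, so the counts were read as human. The human build and annotation version are not stated, so no coordinates are given. How barcodes were filtered before deposit is not stated, and the lowest total of any barcode was 500 UMIs. The mCherry reporter is not among the features.

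All 5 libraries were used. Y-linked genes, XIST and TSIX (103 genes) were left out before any total was made. Cells with at least 500 genes and at most 20% mitochondrial UMIs (13 genes) were kept. Scrublet, run per library with 30 components and an expected share of 0.8% per 1000 cells, marked 1 cell in fresh 1, 0 in fresh 4, 5 in expanded 2, 1 in expanded 3 and 0 in expanded 5. These were removed, but so few marks mean that the caller has not worked, so doublets remain among the kept cells. In an alternative, the 483 cells with the highest scores were removed instead. Kept cells summed to between 24585001 UMIs in expanded 2 and 58590441 in fresh 4. Comparing gene totals between pairs of libraries by chi-square gave 230.2 to 463.9 per degree of freedom, so no library repeats another.

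Cells were clustered with scanpy 1.11.5 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, leidenalg 0.10.2) on 2000 variable genes and 30 principal components, with 20 neighbours, Leiden resolution 1 and seed 1, without integrating libraries. Cluster names came from 19 lists of marker genes. A marker counted as detected when at least 25% of the cluster's cells had a UMI. A cluster stayed unnamed with fewer than 3 detected markers, with more markers of another list than of its own among its 10 leading genes by fold (10 CPM added), or at low depth with none of its own markers there. Shares per library have exact (Clopper-Pearson) 95% intervals, which cover counting error only, and a share of 0 is given with the limit that 3 counts allow. Groups were compared by two-sided exact permutation tests over the 10 splits of the libraries, where the smallest possible p is 0.2. Shares of cells with a TOP2A or MKI67 UMI were taken after thinning each cell to 2000 UMIs, leaving out shallower cells.

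For tests across genes, counts were summed per library, since cells are not replicates. The main test was edgeR 4.0.16's quasi-likelihood F test (R 4.3.3; TMM scaling, filterByExpr, robust, 3 residual degrees of freedom), expanded minus fresh, with Benjamini-Hochberg adjustment and a threshold of 0.05. The common dispersion was 0.355, a biological coefficient of variation of 0.596. The same test was run within the 1 class with at least 50 cells in every library. The 35 gene lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation and with fry. The erythroid list had no gene past the filter and was not tested, leaving 34. The lists, the marker lists, the tests and the rule for naming genes were fixed before the data were examined. That rule names CDX2, EOMES, ELF5 and the reporter, the 12 largest rises and 12 largest falls among called genes of at least 50 mean CPM whose groups do not overlap (8 and 8 for a class), and the 4 most abundant members of each list. As no gene was called, the 12 genes per direction shown instead were chosen after their values were seen, as were other genes said to be so, and cluster-leading genes follow from the clustering. Members called when adjusted over the list alone are also named.

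The tests were tried on simulated counts with known changes. At the spread of the real libraries edgeR recovered 0% of changed genes at a log2 of 1, 2 and 3 (63, 62 and 63 genes, 18707 genes in all), and called 1 unchanged gene. For the class it recovered 0% (64, 64 and 66 genes, 15921 in all). At a dispersion of 0.02 it recovered 69.2%, 100% and 100% of 18841 genes' changed members at the same sizes.

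Alternatives tried for the counts of genes were RLE scaling, DESeq2 1.42.0, limma-voom, no low-count filter, all deposited barcodes, at most 10% mitochondrial UMIs, at least 1000 genes per cell, called doublets kept, libraries thinned to equal depth, 909 cells per library, no immune-like cells, no mitochondrial genes, and each library left out in turn. For the class and the shares, Leiden resolutions 0.5 and 2 were also tried, and for cycling cells thinning to 1000 and 5000 UMIs and no thinning. Added after seeing the data were removal of cells with the highest doublet scores, thinning of each cell to 2000 UMIs before summing, removal of cells with a TOP2A or MKI67 UMI, removal of cells outside the stromal-marker clusters, and cells of at least 2000 UMIs with expanded 2 left out. Also added were a class of all clusters with most stromal markers, and libraries left out in turn for the shares.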

Results

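The series profiled single cells from human term placenta, the organ at the end of pregnancy. Chorionic cells were sorted as positive for mCherry, a red fluorescent reporter linked to CDX2, a homeobox factor of the early trophoblast lineage. Freshly isolated cells (2 libraries, fresh 1 and fresh 4) were set against cells expanded in culture to passage 3 (3 libraries, expanded 2, expanded 3 and expanded 5), and all 5 were thawed before loading. The title places the cells in the setting of cardiovascular repair, so the comparison asks what expansion does to the sorted cells. The labels do not say whether libraries of a group came from separate donors or cultures, so p-values here measure only the spread between these samples, which may be technical.

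The deposited counts held 19594 barcodes, of which 15575 were kept (at least 500 genes, at most 20% mitochondrial UMIs). Fresh 1 kept 5525 of 6169 barcodes, fresh 4 kept 3650 of 4048, expanded 2 kept 909 of 1604, expanded 3 kept 2208 of 3736 and expanded 5 kept 3283 of 4037. The design text aimed at about 3000 cells per library. Barcodes above 20% mitochondrial UMIs made up 9.55% and 9.51% of the fresh libraries, against 27.5%, 40.3% and 18.6% of expanded 2, 3 and 5. Kept cells held a median of 8217 UMIs in fresh 1, 14354.5 in fresh 4, 9660 in expanded 2, 14833 in expanded 3 and 14198 in expanded 5. Over kept cells this summed to 51918079, 58590441, 24585001, 34040154 and 52396024 UMIs in the same order.

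Most cells of both groups carried stromal, that is fibroblast or mesenchymal, transcripts. COL1A1, the main chain of type I collagen, was detected in 97.2% and 99.0% of fresh cells and in 83.3%, 92.7% and 98.4% of the cells of expanded 2, 3 and 5. PDGFRA, a growth factor receptor of fibroblasts, was detected in 58.8% and 67.9% of fresh cells and in 33.2%, 64.1% and 88.0% of expanded cells. THY1, a mesenchymal surface glycoprotein, was found in 67.3% and 71.0% of fresh cells and in 17.8%, 87.1% and 84.5% of expanded cells. For comparison, the macrophage-like cells of all libraries (43 cells, median 5469 UMIs) gave 32.6% for COL1A1 and 9.30% for both PDGFRA and THY1. Their 180 COL1A1 UMIs lay in 14 of the 43 cells. Such shares therefore need not measure free RNA alone, since doublets also remain among the kept cells. The epithelial surface protein EPCAM was seen in 0.489% and 4.90% of fresh cells and in 0.453% to 0.660% of expanded cells, with 0 of 43 macrophage-like cells, which allows a share of up to 6.98%. KRT7, a keratin of trophoblast and simple epithelia, was more widespread, in 13.9% and 12.99% of fresh cells and in 12.9%, 11.55% and 8.498% of expanded 2, 3 and 5 cells, against 2.33% of the shallower macrophage-like cells. CGA, the alpha chain of chorionic gonadotropin, was seen in 0.525% and 0.548% of fresh cells. It was seen in 0.11% and 0.0609% of cells of expanded 2 and 5 and in 0 of 2208 cells of expanded 3, which allows a share of up to 0.136%.

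**Figure D1:**
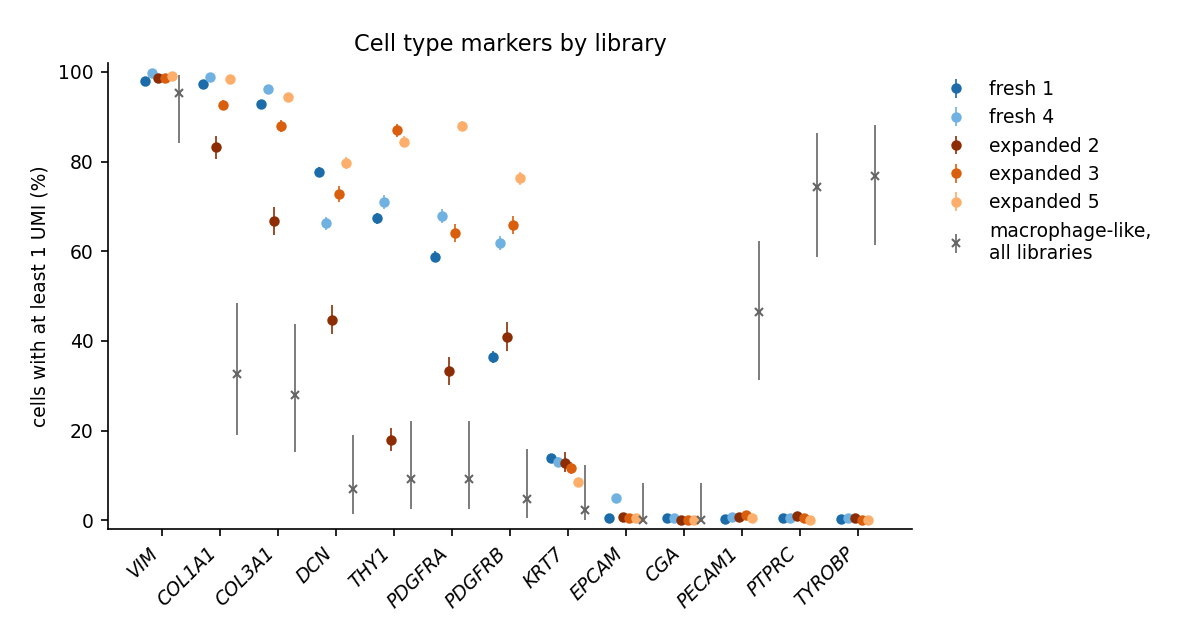
Share of kept cells with at least 1 UMI (%, y axis) of 13 marker genes (x axis) in each library and in the macrophage-like cells of all libraries, with exact 95% binomial intervals. COL1A1 lies between 83.3% and 99.0% in the 5 libraries, and PTPRC below 1% in all 5 but at 74.4% in the macrophage-like cells.

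Clusters were named from markers fixed before the data were examined. Of 27 clusters, 25 had the fibroblast or mesenchymal stromal list as their most detected, with 4 to 13 of its 16 markers. These clusters held 99.4% and 97.5% of the fresh cells and 99.7%, 100% and 99.97% of the expanded cells of libraries 2, 3 and 5. Their means were 98.4% ± 1.35 (SD, n = 2) and 99.9% ± 0.182 (SD, n = 3), a difference of 1.45 points (two-sided exact permutation test, p = 0.2, the smallest the 10 splits allow). Only 14 of them met the stricter naming rule, because leading genes of another cell type or low depth left 11 unnamed. Under that rule the stromal-like share was 90.4% in fresh 1 and 25.2% in fresh 4, against 55.7%, 23.05% and 5.36% in expanded 2, 3 and 5 (exact permutation p = 0.4). The unnamed clusters with most stromal markers held 9.03% and 72.3% of fresh cells and 44.0%, 77.0% and 94.6% of expanded cells. The difference between group means under the strict rule, -29.8 points (57.8% ± 46.1, SD, n = 2, against 28.0% ± 25.5, SD, n = 3), was 2.82 points without fresh 1 and -62.3 without fresh 4, so 1 fresh library decided it. It was -18.4 points without expanded 5, -12.3 and -16.9 at coarser and finer clustering and -15.6 with called doublets kept.

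A small cluster was macrophage-like, led by SPP1, HLA-DRA, LYZ, FCER1G, TYROBP and the complement genes C1QB and C1QC. It held 0.344% of fresh 1 (19 cells), 0.548% of fresh 4 (20 cells), 0.330% of expanded 2 (3 cells) and 0.0305% of expanded 5 (1 cell). In expanded 3 it held 0 of 2208 cells, which allows a share of up to 0.136%. The means were 0.446% ± 0.144 (SD, n = 2) and 0.1202% ± 0.182 (SD, n = 3), a difference of -0.326 points (exact permutation p = 0.2). It was -0.224 points without fresh 4. An unnamed cluster of 87 cells was led by MMP7, KRT7, LAMC2, LAMB3 and SPINT2, genes of epithelia and their basement membrane. It carried 6 of the 11 amnion epithelial markers, but 0 of these were among its leading genes. Because 2 leading genes were markers of another list, the cluster stayed unnamed. As KRT7 is also a keratin of trophoblast, a trophoblast identity of the cluster is not excluded. Its cells came from fresh 4 (72) and fresh 1 (15). The cells had been sorted on the reporter, so such shares describe the sorted fraction and not the placenta.

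CDX2 transcript (ENSG00000165556), the gene behind the sort, was scarce in every library and did not separate the groups. It gave 116 UMIs in fresh 1 and 16 in fresh 4, against 13, 61 and 34 in expanded 2, 3 and 5. Cells with a CDX2 UMI made up 1.99% of fresh 1 (exact 95% interval 1.64 to 2.40%) and 0.438% of fresh 4 (0.251 to 0.711%). In the expanded libraries they made up 1.32% (0.684 to 2.29%), 2.72% (2.08 to 3.48%) and 1.005% (0.693 to 1.41%) in the order 2, 3 and 5. In macrophage-like cells, assumed and not tested to lack the gene, since they passed the same sort, 1 of 43 cells had a UMI (2.33%, 0.0589 to 12.3%, median 5469 UMIs, against 8217 to 14833 in the libraries), so only the share of expanded 3 lay above theirs, whose interval covers all 5 shares. Group means were 1.22% ± 1.10 (SD, n = 2) and 1.68% ± 0.911 (SD, n = 3), a difference of 0.466 points (two-sided exact permutation test, p = 0.8). In CPM (UMIs scaled to a common library total) the level was 2.23 and 0.273 in fresh and 0.529, 1.79 and 0.649 in expanded libraries, and edgeR gave a log2 fold change of -0.05 (SE 1.08, adjusted p = 0.999). The difference in shares was -0.310 points without fresh 4, 1.24 without fresh 1 and -0.0522 without expanded 3. It was -0.0310 over all barcodes and -0.0872 with each cell thinned to 2000 UMIs. The reporter itself was not among the listed genes.

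**Figure D2:**
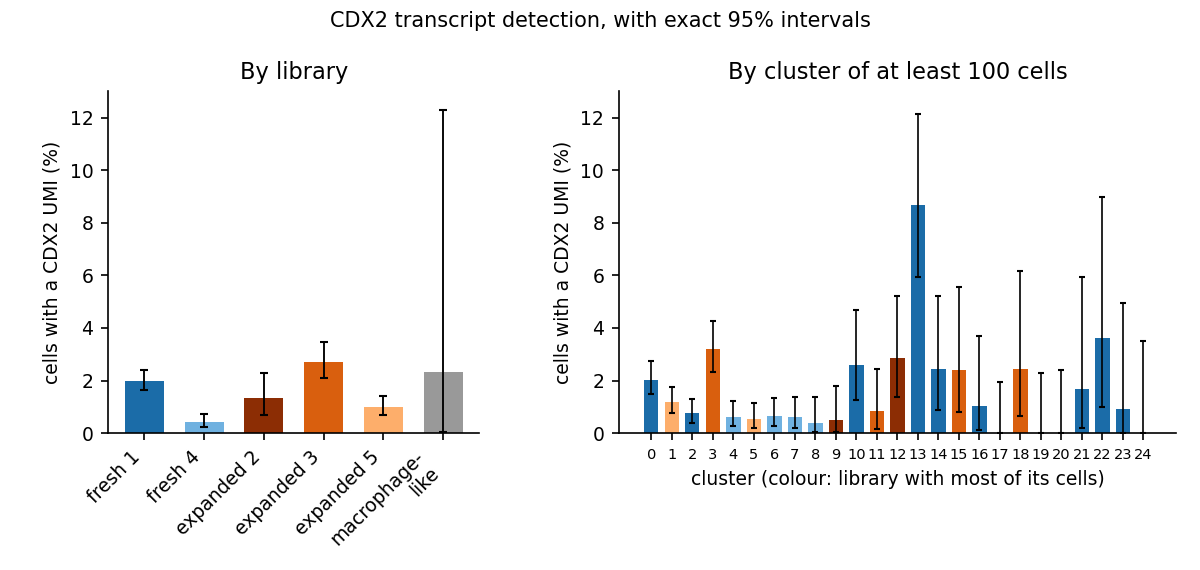
Share of cells with at least 1 CDX2 UMI (%, y axes) by library and in macrophage-like cells (left) and by cluster of at least 100 cells (right, coloured by the library that gave most of its cells), with exact 95% binomial intervals. Library shares run from 0.438% to 2.72%, and cluster 13, from fresh 1, stands at 8.67%.

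EOMES and ELF5, listed with CDX2 among the early trophoblast genes, gave almost no UMIs. EOMES (ENSG00000163508) had a UMI in 0 of 15575 kept cells, which allows a share of cells with a UMI of up to 0.0193% and sets no limit on cells that express it below detection. ELF5 (ENSG00000135374) had 2 UMIs, both in 1 cell of fresh 1. Other early trophoblast factors were seen in minorities of cells. TFAP2C was found in 1.74% and 6.82% of fresh cells and in 0, 4.76% and 11.2% of expanded 2, 3 and 5 cells, where 0 of 909 cells allows up to 0.330%. GATA3 was found in 1.38% of fresh 1 and 0.0274% of fresh 4 cells and in 0 of 909, 0 of 2208 and 0 of 3283 expanded cells, which allow up to 0.330%, 0.136% and 0.0914%. TEAD4 was found in 12.9% and 9.92% of fresh and in 14.6%, 4.67% and 9.53% of expanded cells. In macrophage-like cells TFAP2C and GATA3 had no UMI in 43 cells, which allows up to 6.98%, and TEAD4 was found in 4.65%. Only the TFAP2C share of expanded 5, and the TEAD4 shares of every library but expanded 3, which was level with it, lay above these values, and the libraries were deeper than the macrophage-like cells.

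Stromal cells of different libraries formed different clusters. Of the 27 clusters, 21 took over 90% of their cells from 1 library. Fresh 1 was made largely of cells led by HGF and EGFL6, encoding a hepatocyte growth factor and an EGF-like matrix protein (2110 cells), and of cells led by KRT81, TENM2 and the Wnt antagonist DKK2 (1575 cells). Fresh 4 was led by PSG4, CD24 and STMN2 (1252 cells), by the mitotic genes CENPF, TOP2A and MKI67 (912 cells) and by GREM2, a BMP antagonist, and FOXO1 (835 cells). Expanded 3 was led by CCL2, CST1, CHI3L1 and OXTR (1358 cells), and expanded 5 by PSG1, MGP and MMP10 (1926 cells) and by IGF1 and PGR (1127 cells). In expanded 2, 344 cells led by PTX3, ANKRD1 and KRT18 held 82.0% of its UMIs at a median of 60909.5 UMIs, while 398 cells led by CDKN2A held 6.45% at a median of 1319.5. PSG genes are near-identical copies, so reads may have been split among them. Over 19203 genes, log expression of fresh 4 had a Pearson correlation of 0.923 with fresh 1, against 0.944 and 0.948 with expanded 3 and 5. Expanded 3 and 5 correlated at 0.956 with each other and at 0.885 and 0.854 with expanded 2. These correlations are across genes, which are not independent replicates. The first principal component (49.7% of the variance) set expanded 2 (-147.3) apart from the other libraries (-38.4 and 42.3 for fresh 1 and 4, 57.9 and 85.5 for expanded 3 and 5).

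Among abundant genes that separated every expanded from every fresh library, ITGA11, OXTR, GAS6 and IGFBP7 were higher after expansion, and ID1, an inhibitor of differentiation downstream of BMP signals, was lower. These genes were chosen after their values were seen, as the lowest unadjusted p among non-overlapping genes with a mean of at least 50 CPM. ITGA11 (ENSG00000137809), a collagen-binding integrin chain, stood at 13.3 and 20.3 CPM in fresh libraries and at 182, 96.9 and 93.1 in expanded ones (log2 3.12, SE 0.51). OXTR (ENSG00000180914), the oxytocin receptor, stood at 16.0 and 4.98 against 69.8, 243 and 74.1 (log2 3.91, SE 0.98). GAS6 (ENSG00000183087), a ligand of TAM receptor kinases, stood at 58.0 and 57.5 against 538, 619 and 120.5 (log2 3.18, SE 0.88). IGFBP7 (ENSG00000163453), a secreted IGF-binding protein, stood at 1616 and 1398 against 5036, 3598 and 3602 (log2 1.67, SE 0.43). MGAT5, a glycan-branching enzyme, had a log2 fold change of 1.87 (SE 0.36), CD9, a tetraspanin, 1.80 (SE 0.46) and the sodium channel SCN9A 4.12 (SE 1.06). ID1 (ENSG00000125968) stood at 245 and 171 in fresh against 37.7, 16.2 and 18.6 in expanded libraries (log2 -2.87, SE 0.48). ITGA1, another collagen-binding integrin chain, had a log2 fold change of -1.11 (SE 0.34), the AP-1 subunit FOSL1 -0.82 (SE 0.26), and the fatty acid desaturases FADS1 and SCD -0.93 (SE 0.26) and -0.79 (SE 0.26).

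**Figure D3:**
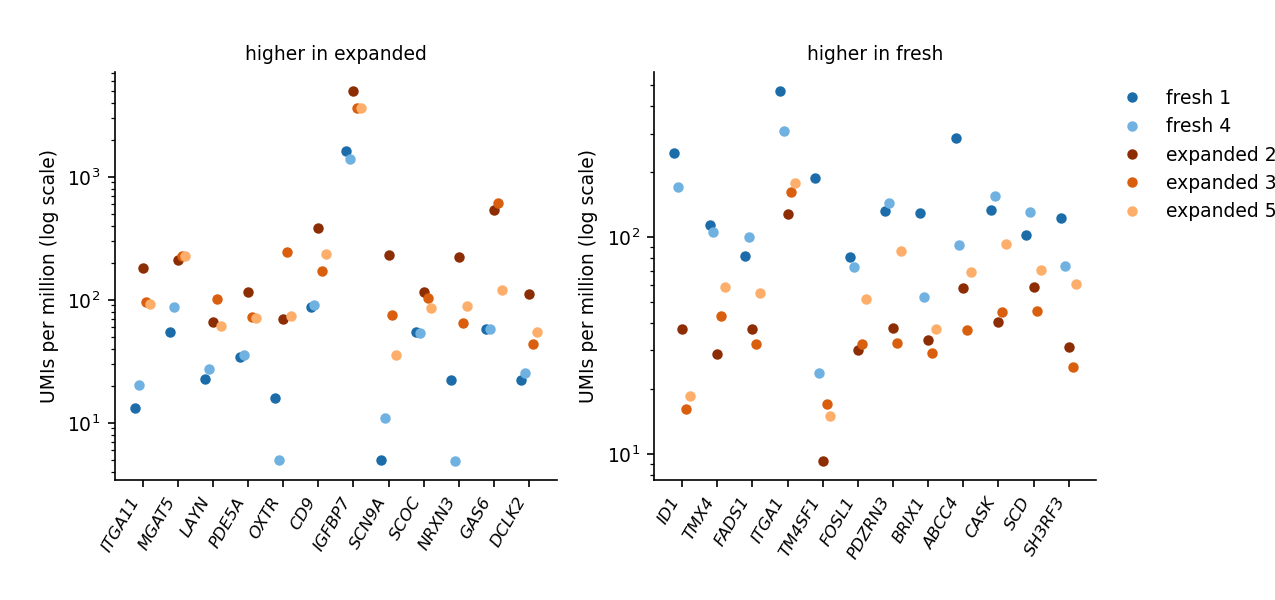
CPM in each library (y axes, log scale) for 12 genes higher in the expanded libraries (left) and 12 higher in the fresh libraries (right), chosen after their values were seen. ITGA11 lies at 93.1 to 182 in expanded and 13.3 to 20.3 in fresh libraries, and ID1 at 16.2 to 37.7 against 171 to 245.

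None of these differences passed the main test. The edgeR quasi-likelihood test called 0 of 19203 genes at an adjusted p under 0.05 (812 had an unadjusted p under 0.05), and every gene's adjusted p was at least 0.999. Of the other tools, limma-voom called 0 and DESeq2 called 176 (78 higher, 98 lower in expanded), 173 of them with no overlap between the groups. DESeq2's adjusted p was 1.28e-05 for ITGA11, 0.000498 for ID1, 0.000373 for MGAT5, 0.00217 for OXTR, 0.00254 for IGFBP7 and 0.0145 for GAS6. It was 0.00243 for SCN9A and 0.0322 for CD9. DESeq2 did not call ITGA1 (0.153), FOSL1 (0.359), FADS1 (0.207) or SCD (0.380), so among the named genes lower in expanded libraries it called ID1 only. In all, 3733 genes (19.4%) did not overlap between the groups, where chance gives 20% for 2 against 3 libraries, and 2922 of them were lower in expanded cells. In counts simulated at the spread of these libraries, edgeR recovered 0% of genes changed by a log2 of 1, 2 or 3, so a count of 0 at this spread excludes no change of that size. Log2 folds come from a fit with scaled library sizes, so for a few genes near 0 their sign differs from that of the difference in mean CPM.

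Proliferation genes were lower in the expanded libraries. All 24 genes of the mitosis list had negative log2 folds, with a median of -1.57, and camera placed the list below other genes (adjusted p = 1.17e-28, and adjusted p = 0.419 with an estimated correlation). Without fresh 4 the median was -0.83. None of the 24 passed over all genes, and 23 did when adjusted over the list alone. CDK1, the kinase that starts mitosis, stood at 32.2 and 34.3 CPM in fresh against 8.58, 6.90 and 14.6 in expanded libraries (log2 -1.55, SE 0.31). UBE2C, which marks mitotic regulators for degradation, had a log2 fold change of -1.40 (SE 0.37), CENPF, a kinetochore protein, -1.64 (SE 0.56), HMGB2 -1.10 (SE 0.42) and PTTG1, the securin, -0.89 (SE 0.31). The S phase list, genes of DNA replication, had a median of -1.31 over 24 genes (camera adjusted p = 6.06e-20, and adjusted p = 0.419 with an estimated correlation), and 3 of them, CDC45, RRM2 and CDT1, passed when adjusted over the list alone. Its median was -0.69 without fresh 4. TYMS, the thymidylate synthase, had a log2 fold change of -1.42 (SE 0.42), RRM1 -0.82 (SE 0.43), PCNA -0.61 (SE 0.39) and SLBP -0.09 (SE 0.23).

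Shares of cycling cells went the same way. With each cell thinned to 2000 UMIs, 5.43% of fresh 1 cells (exact 95% interval 4.84 to 6.09%) and 13.3% of fresh 4 cells (12.2 to 14.4%) had a UMI of TOP2A or MKI67, both markers of dividing cells. The shares were 1.62% (0.777 to 2.95%), 2.06% (1.51 to 2.75%) and 2.51% (2.00 to 3.11%) in expanded 2, 3 and 5. Thinning left out 300 and 47 shallower fresh cells and 290, 24 and 17 expanded cells. Group means were 9.35% ± 5.54 (SD, n = 2) and 2.06% ± 0.448 (SD, n = 3), a difference of -7.29 points (two-sided exact permutation test, p = 0.2, the smallest this design allows). Without thinning the shares were 12.3% and 27.5% against 5.17%, 5.30% and 6.79%. Among the macrophage-like cells 1 of 43 (2.33%, exact 95% interval 0.0589 to 12.3%, median 5469 UMIs) had such a UMI without thinning. That share lay below every library, but its interval covers the shares of the expanded libraries, and all libraries were deeper. The size depended on the fresh libraries: the difference was -3.37 points without fresh 4 and -11.2 without fresh 1. Likewise the adjusted p of the mitosis list was 2.84e-05 without fresh 4 and at most 2.36e-17 without any other library, and that of the S phase list 0.00123 and at most 1.81e-13.

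**Figure D4:**
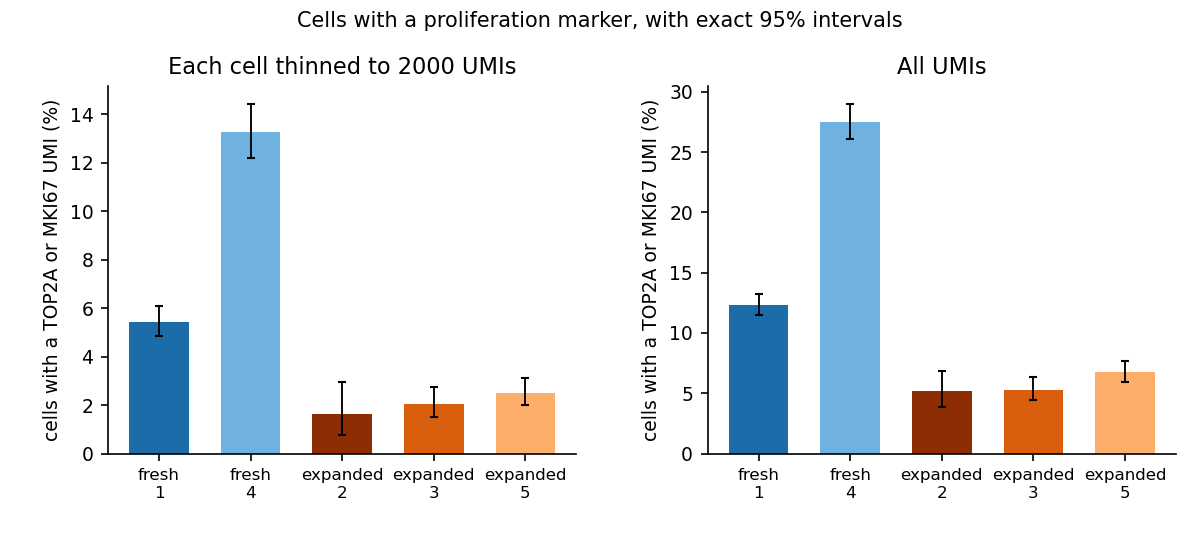
Share of cells with a UMI of TOP2A or MKI67 (%, y axes) in each library, with each cell thinned to 2000 UMIs (left) and with all UMIs (right), and exact 95% binomial intervals. At equal depth the fresh libraries stand at 5.43% and 13.3% and the expanded ones at 1.62% to 2.51%.

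Contractile and matrix genes were higher in expanded libraries as lists. The 20 genes of smooth muscle and the actin cytoskeleton had a median log2 of 0.53 (camera adjusted p = 3.48e-05, adjusted p = 0.555 with an estimated correlation), and this call remained with any 1 library left out (adjusted p from 1.50e-06 to 0.0149). The size was less stable: the median was 0.22 without expanded 3, 0.35 without fresh 1 and 0.33 with each cell thinned to 2000 UMIs. TAGLN, an actin-bundling protein of smooth muscle, averaged 3764 ± 1051 CPM (SD, n = 2) in fresh and 7718 ± 3784 (SD, n = 3) in expanded libraries (log2 1.30, SE 0.62). TPM2 had a log2 of 1.22 (SE 0.65), CALD1 0.76 (SE 0.52) and TPM1 0.34 (SE 0.47). The 28 collagen and matrix genes had a median of 0.65 (camera adjusted p = 0.000180, adjusted p = 0.555 with an estimated correlation), from 2.75e-07 to 0.0471 with another library left out and 0.266 without fresh 4. Its median was 0.23 without expanded 3. COL1A2 averaged 1905 ± 76.3 (SD, n = 2) against 3613 ± 1351 (SD, n = 3) CPM (log2 1.17, SE 0.51), and COL1A1, fibronectin FN1 and SPARC had log2 folds of 1.05 (SE 0.65), 1.58 (SE 0.86) and 0.98 (SE 0.54). Surface markers of mesenchymal stromal cells, 13 genes, had a median of 0.58 (camera adjusted p = 0.00140, adjusted p = 0.419 with an estimated correlation), and 0.148 without fresh 4 against at most 0.0138 without another library. Among them the integrin chain ITGB1 stood at 868 and 1149 in fresh and at 1992, 2047 and 1626 in expanded libraries (log2 1.15, SE 0.41), while NT5E, CD63 and CD44 had log2 folds of 0.58 (SE 0.38), 0.14 (SE 0.43) and -0.15 (SE 0.37). Matrix remodelling enzymes and inhibitors, 20 genes, were not called (median 0.48, camera adjusted p = 0.0826), but were without fresh 1 (0.0112, against 0.0651 to 0.682 without another library). In that list TIMP1 had a log2 of 2.10 (SE 1.25), SERPINE1 0.99 (SE 0.79), SERPINE2 -0.72 (SE 0.96) and TIMP3 -0.81 (SE 1.83). No member of these 4 lists passed, whether over all genes or adjusted over the list alone.

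**Figure D5:**
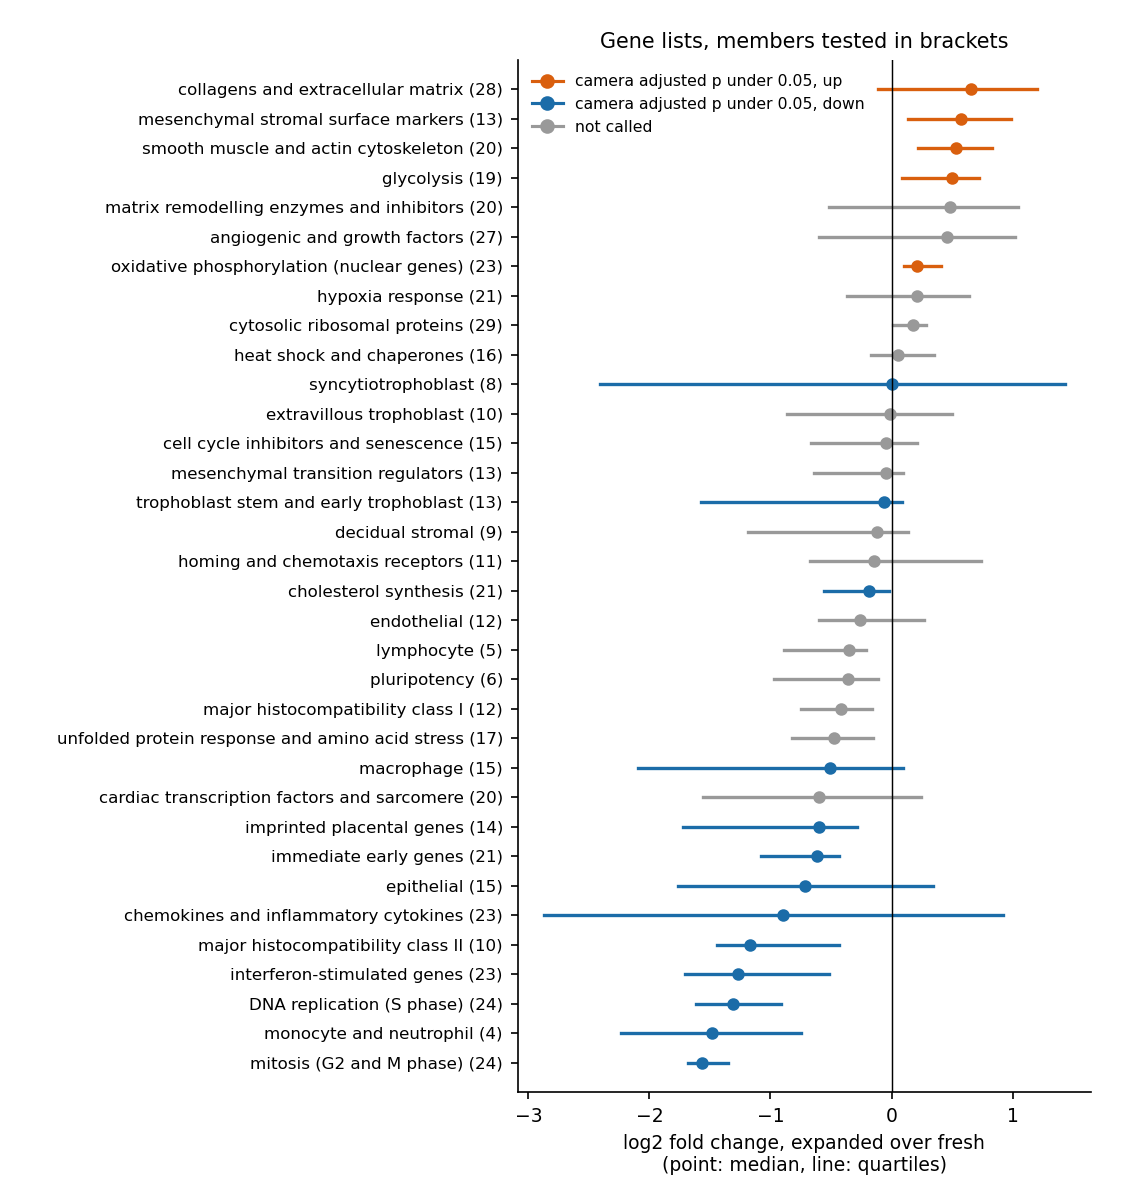
Median (point) and quartiles (line) of log2 fold changes, expanded over fresh (x axis), of 34 gene lists (y axis, with the number of genes tested), coloured by the call of camera with a preset correlation of 0.01. The medians run from 0.65 for collagens to -1.57 for mitosis, and no list is called with an estimated correlation.

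Energy metabolism differed by small amounts that single libraries decided. Glycolysis genes (19) had a median log2 of 0.50 (camera adjusted p = 0.0270, adjusted p = 0.668 with an estimated correlation), with LDHA, which makes lactate, at 1.10 (SE 0.67), GAPDH at 0.74 (SE 0.72), TPI1 at 0.73 (SE 0.52) and PKM at 0.68 (SE 0.65). That call ended without expanded 2 (0.258), expanded 3 (0.394) or fresh 4 (0.265), against 2.76e-05 without expanded 5, and with each cell thinned to 2000 UMIs (0.152). Its median was 0.17 without expanded 2 and 0.18 without expanded 3. Nuclear genes of oxidative phosphorylation (23) had a median of 0.21 (camera adjusted p = 0.0307, adjusted p = 0.668 with an estimated correlation), with NDUFA4 at 0.75 (SE 0.41), COX7C at 0.50 (SE 0.34), COX5B at 0.47 (SE 0.39) and COX4I1 at 0.25 (SE 0.38). It ended without expanded 2 (0.575), expanded 3 (0.0734) or fresh 1 (0.430), against 0.00131 without expanded 5, with each cell thinned (0.165), without cycling cells (0.0711) and in stromal-marker clusters alone (0.0534). Its median was 0.05 without expanded 2 and 0.11 without fresh 1, against 0.40 without expanded 5 and 0.39 without fresh 4. Cholesterol synthesis genes (21) had a median of -0.18 (camera adjusted p = 0.00803, adjusted p = 0.668 with an estimated correlation), which ended without expanded 3 (0.307), expanded 5 (0.223) or fresh 4 (0.350), against 1.52e-08 without expanded 2. The median was 0.03 without expanded 3, 0.04 without fresh 4 and -0.08 without expanded 5, against -0.80 without expanded 2 and -0.36 without fresh 1. Its abundant members FDPS, MSMO1, CYP51A1 and FDFT1 had log2 folds of 0.17, 0.23, 0.09 and -0.35, with SEs of 0.33 to 0.68. Hypoxia response genes (21) were not called (median 0.21, camera adjusted p = 0.249), with BNIP3 at 0.67 (SE 0.57), P4HA2 at 0.47 (SE 0.43) and ADM at -0.18 (SE 0.84), but were higher without fresh 1 (0.000127, median 0.88, against 0.0803 to 0.677), and camera's direction was downward without fresh 4 (0.185, median -0.16) or expanded 3 (0.677, median 0.04). Cytosolic ribosomal proteins (29) were not called (median 0.17, camera adjusted p = 0.196), but were higher without expanded 5 (0.0140, against 0.0747 to 0.805), and turned downward without expanded 3 (median -0.06, 0.470). RPLP1, RPL13, RPS18 and RPS19 had log2 folds of 0.38, 0.25, 0.24 and 0.06 (SE 0.40 to 0.48), and their many pseudogenes make such counts uncertain. Heat shock genes and chaperones (16) were not called (median 0.06, camera adjusted p = 0.202), with HSPB1 at 0.88 (SE 0.48) and HSP90B1, HSP90AA1 and HSP90AB1 at 0.23, 0.04 and -0.20. Genes of the unfolded protein response and amino acid stress (17) were not called (median -0.48, camera adjusted p = 0.101), with SLC3A2 at -0.87 (SE 0.80) and PDIA6, MANF and HERPUD1 at -0.15, -0.18 and 0.07. They turned upward without fresh 1 (median 0.58, 0.195). They were lower without fresh 4 (0.000559, median -1.06, against 0.0690 to 0.677), without cycling cells (0.0448) and with each cell thinned (0.0170).

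Named genes of acute activation and interferon were highest in fresh 1, and the list results depended on it. Immediate early genes (21) had a median log2 of -0.61 (camera adjusted p = 7.68e-05, adjusted p = 0.580 with an estimated correlation). FOS, an AP-1 subunit, stood at 610 CPM in fresh 1, 184 in fresh 4 and 176, 108 and 301 in expanded libraries (log2 -0.85, SE 0.60), and IER3, DUSP1 and JUND had log2 folds of -0.73 (SE 0.56), -0.60 (SE 0.63) and -0.41 (SE 0.41). Without fresh 1 the list turned upward with an adjusted p of 0.805 (median -0.02), against 4.29e-10 to 0.0116 without another library, and its median was -1.008 without fresh 4. Interferon-stimulated genes (23) had a median of -1.27 (camera adjusted p = 0.00712, adjusted p = 0.668 with an estimated correlation). IFI27 stood at 2627 in fresh 1, 79.3 in fresh 4 and 310, 335 and 847 in expanded libraries (log2 -1.28, SE 1.24), the ubiquitin-like modifier ISG15 at 1072, 135, 265, 63.4 and 308 (log2 -1.33, SE 0.97), and IFI6 and IFITM3 had log2 folds of -1.45 (SE 1.44) and -0.23 (SE 0.86). IFITM genes are near-identical copies. Without fresh 1 camera called the list upward (adjusted p = 2.01e-06, median 1.21), and without expanded 2 it was not called (0.499, median -0.99), while without fresh 4 it was lower (3.47e-16, median -2.12). Without expanded 5 the median was -1.95. Chemokines and inflammatory cytokines (23) had a median of -0.90 (camera adjusted p = 0.00803, adjusted p = 0.666 with an estimated correlation), and the call ended without fresh 1 (0.756), expanded 2 (0.0565) or expanded 5 (0.378), against 6.72e-06 without expanded 3, and with each cell thinned (0.0711) or in stromal-marker clusters alone (0.481). Its median was -0.09 without fresh 1 and -0.53 without expanded 5, against -1.78 without expanded 3. Its most abundant member, the monocyte attractant CCL2 (ENSG00000108691), went against the list, at 22.0 and 20.2 in fresh and 68.9, 564 and 98.8 in expanded libraries (log2 3.85, SE 1.20), and IL6, CSF1 and CXCL8 had log2 folds of 1.35 (SE 0.97), -0.39 (SE 0.74) and -0.53 (SE 0.72). No member of these lists passed, also when adjusted over the list alone.

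Immune cell and antigen presentation genes can come from the few macrophage-like cells, whose share was 0.344% and 0.548% in fresh and 0.330%, 0 and 0.0305% in expanded libraries. Macrophage genes (15) had a median of -0.51 (camera adjusted p = 7.68e-05, adjusted p = 0.419 with an estimated correlation) and lost the call without fresh 4 (0.205, against 6.14e-16 to 0.0389) and in stromal-marker clusters alone (0.570, 6 genes tested). Its median was 0.50 without fresh 4 (6 of 14 genes below 0), -4.79 without expanded 2, -0.33 without expanded 3 and -0.11 without expanded 5. With 909 cells from each library it was 0.16, with 4 of 11 genes below 0, so its sign is not settled. CD68, a lysosomal protein that stromal cells also express, stood at 44.5 and 30.3 in fresh and 19.3, 19.9 and 29.4 CPM in expanded libraries (log2 -0.51, SE 0.28), and CD14, FCER1G and TYROBP had log2 folds of 0.16 (SE 0.61), 0.03 (SE 1.58) and 0.28 (SE 2.32). Genes of MHC class II, which presents antigen to T cells, had a median of -1.17 over 10 genes (camera adjusted p = 0.00192, adjusted p = 0.596 with an estimated correlation), lost without fresh 4 (0.284) or expanded 5 (0.175), against 1.52e-12 without expanded 2. The median was -3.71 without expanded 2, -0.63 without expanded 3, -0.62 without expanded 5 and -0.09 without fresh 4. With 909 cells from each library it was 0.77 (3 of 7 genes below 0), so this list has no settled sign either. In stromal-marker clusters alone, which leave out the macrophage-like cells, the class II list was still called lower (camera adjusted p = 0.0284). HLA-DPB1 stood at 5.97 and 20.3 against 2.81, 3.08 and 3.87 (log2 -1.80, SE 0.56), CD74, HLA-DRA and HLA-DMA had log2 folds of -1.15 (SE 0.66), -1.18 (SE 2.38) and 1.20 (SE 0.74). Monocyte and neutrophil genes (4 tested) had a median of -1.49 (camera adjusted p = 0.0433, adjusted p = 0.443 with an estimated correlation), lost without fresh 4 (0.138) or expanded 5 (0.180), against 0.000283 without expanded 2, and with each cell thinned (0.0711). The median was -0.79 without fresh 4, -2.58 without fresh 1 and -4.44 without expanded 2. Its members G0S2, LYZ, S100A9 and CSF3R had log2 folds of -0.18 (SE 0.50), -2.86 (SE 2.16), -2.03 (SE 2.19) and -0.94 (SE 1.53). MHC class I genes (12) were not called (median -0.41, camera adjusted p = 0.0570), with B2M, HLA-C, HLA-B and HLA-A at 0.17, -0.31, -0.39 and -0.44 (SE 0.54 to 0.79). They turned upward without fresh 1 (median 0.31, 2 of 12 genes below 0, adjusted p = 0.340). They were lower without fresh 4 (0.000254) or expanded 5 (0.0170), against up to 0.661 without expanded 2, with each cell thinned (0.0111) and without cycling cells (0.0217). HLA genes share reads with one another, so their levels are uncertain. Lymphocyte genes (5 tested) were not called (median -0.35, camera adjusted p = 0.584), with IL7R at -1.14 (SE 0.51), KLRD1 at 1.22 (SE 0.48), TRAC at -0.21 (SE 0.67) and PTPRC at -0.89. Erythroid genes were too scarce to test: CA1, the most abundant, reached 0.212 CPM in fresh 1, and none of the 11 passed the count filter. No member of these lists passed, also when adjusted over the list alone.

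Camera called trophoblast and epithelial lists lower in expanded libraries, though their members went both ways. With the 130 cells outside the stromal-marker clusters left out, the calls of early trophoblast and epithelial genes ended, and syncytiotrophoblast (0.00652) and imprinted genes (0.00462) were still called lower. Early trophoblast genes (13) had a median log2 of -0.06 and a mean of -0.53 (camera adjusted p = 0.00803, adjusted p = 0.419 with an estimated correlation), lost without fresh 1 (0.338) or expanded 5 (0.0690), against 0.00648 without fresh 4, and in stromal-marker clusters alone (0.0534). Its median was -0.15 without fresh 1, -0.77 without fresh 4, and -1.13, -0.61 and -0.56 without expanded 2, 3 and 5. KRT7 stood at 50.2 and 61.6 in fresh against 29.2, 9.78 and 6.81 CPM in expanded libraries (log2 -1.62, SE 0.68). However, 46.7% of its 7621 UMIs lay outside the stromal-marker clusters, in 14 cells of fresh 1 and 73 of fresh 4. Inside these clusters KRT7 stood at 40.4 and 9.94 in fresh against 29.3, 9.78 and 6.81 CPM, so the groups overlapped (log2 -0.46). ITGA6 had a log2 of -0.04 (SE 0.86). Epithelial genes (15) had a median of -0.71 (camera adjusted p = 0.00712, adjusted p = 0.419 with an estimated correlation), lost without expanded 5 (0.180, against 0.000827 to 0.0162). Its median was -1.48 without expanded 2. In stromal-marker clusters alone the median was -0.10 and the call ended (0.824), so the call depended on the other cells. DSP, a desmosome protein, was higher in expanded libraries (18.5 and 40.6 against 190, 107 and 61.3, log2 2.27, SE 0.69), and KRT18, KRT8 and KRT19 had log2 folds of 1.03 (SE 1.82), 0.09 (SE 1.53) and -0.65 (SE 1.19). KRT8 and KRT18 have many processed pseudogenes, so their counts are uncertain. Syncytiotrophoblast genes (8) had a median of 0.00, just above 0, and a mean of -0.82 (camera adjusted p = 0.0104, adjusted p = 0.419 with an estimated correlation), turning upward without expanded 2 (0.426, against 0.00832 to 0.0276), with 0.332 when each cell was thinned. The median was 0.34 without expanded 2 and 0.82 without fresh 1, against -0.08, -0.41 and -0.93 without fresh 4, expanded 3 and expanded 5. TFPI2, a protease inhibitor, stood at 932 and 710 against 294, 394 and 426 (log2 -0.92, SE 0.34), and PSG4, PSG1 and KISS1 had log2 folds of -3.43 (SE 1.15), 3.20 (SE 1.97) and 0.93 (SE 1.51). CGA (ENSG00000135346) was the 1 member that passed when adjusted over the list alone (0.0277), at 13.7 CPM in fresh 1, 0.70 in fresh 4 and 0.0407, 0 and 0.0382 in expanded 2, 3 and 5. That level rests on few cells: of its 753 UMIs, 661 lay in 2 cells of fresh 1 outside the stromal-marker clusters, and inside these clusters it stood at 0.928 and 0.719 CPM in fresh against 0.0408, 0 and 0.0382 (92 UMIs in 50 cells). Imprinted placental genes (14) had a median of -0.60 (camera adjusted p = 0.00540, adjusted p = 0.555 with an estimated correlation), turning upward without fresh 1 (0.9998, median 0.08, against 2.24e-07 to 0.0427), with a median of -1.24 without fresh 4. PEG10 (ENSG00000242265), a retrotransposon-derived gene needed for placental growth, was the 1 member to pass when adjusted over the list alone (0.0325), at 30.8 and 16.0 against 5.53, 5.14 and 6.24 (log2 -1.83, SE 0.35). PHLDA2, MEG3, PLAGL1 and MEST had log2 folds of 0.78 (SE 0.76), 0.14 (SE 1.28), -0.69 (SE 0.48) and -0.87 (SE 0.92). Extravillous trophoblast genes (10) were not called (median -0.01, camera adjusted p = 0.0747), with DIO2, FSTL3, MMP11 and ITGA1 at 0.58, 0.26, 0.18 and -1.11, but were lower without fresh 4 (0.0309), expanded 3 (0.0373) or expanded 5 (0.0482), against up to 0.499 without expanded 2. Decidual stromal genes (9) were not called (median -0.12, camera adjusted p = 0.214), with PGR, DKK1, HOXA10 and FOXO1 at 1.28, 0.14, -0.23 and -1.19, and turned upward without expanded 2 (median 0.15, 0.791).

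Cardiac, endothelial, angiogenic, homing, pluripotency, cell cycle inhibitor and mesenchymal transition lists gave no call with all 5 libraries. The smooth muscle and matrix lists, described above, were called and are not among them. Cardiac factors and sarcomere genes (20) had a median of -0.60 (camera adjusted p = 0.288) and were lower without fresh 4 (0.00104, median -1.40, against 0.0647 to 0.748). Without fresh 1 they turned upward, with a median of 2.40, 4 of 20 genes below 0 and an adjusted p of 0.0647. Camera's direction was upward without expanded 2 too (0.661), with a median of -0.37, so it is not settled. HAND2, a heart and limb transcription factor also made by decidual stroma, stood at 80.1 and 44.5 in fresh and 6.59, 21.9 and 29.6 CPM in expanded libraries (log2 -1.49, SE 0.61). MEF2A and GATA6 had log2 folds of 0.63 (SE 0.34) and -0.47 (SE 1.23), and the natriuretic peptide gene NPPB stood at 515 in fresh 1 and 257 in expanded 2 against 8.19, 0.382 and 0.534 in fresh 4, expanded 3 and expanded 5. Endothelial genes (12) had a median of -0.26 (camera adjusted p = 0.148) and were lower without expanded 2 (0.0105, against 0.0639 to 0.534), while the median was above 0 without fresh 1 (0.145) or expanded 5 (0.15), with ENG, EGFL7, TEK and FLT1 at 0.12, 0.75, -0.25 and -0.36. Angiogenic and growth factors (27) had a median of 0.46 (camera adjusted p = 0.630), and turned downward without expanded 2 (median -0.14, 0.720) or fresh 4 (median 0.14, 0.2004), with VEGFC at 0.66 (SE 0.37), FGF7 at 0.98 (SE 1.12), FGF2 at -0.57 (SE 0.61) and PDGFC at -0.62 (SE 0.50). Homing and chemotaxis receptors (11) had a median of -0.15, with camera's direction upward (adjusted p = 0.916) but downward without fresh 4, expanded 2 or expanded 3 (0.850, 0.258 and 0.751), and ITGA4 and ACKR3 at 1.07 (SE 0.84) and -1.41 (SE 1.56). Pluripotency genes (6 tested) had a median of -0.36 (camera adjusted p = 0.209) and were lower without expanded 2 (0.0356, against 0.0970 to 0.986) and upward without fresh 1 (median 0.64, 0.986), with MYC, LIN28B, DNMT3B and KLF4 at 0.03, -0.17, -0.56 and -1.57. Cell cycle inhibitors and senescence genes (15) had a median of -0.04 (camera adjusted p = 0.513), although CDKN2A (ENSG00000147889), the p16 inhibitor locus, stood at 64.2 and 34.9 in fresh and 730, 265 and 97.8 in expanded libraries (log2 3.16, SE 1.02). CDKN1A, GADD45A and GDF15 had log2 folds of -0.40, -0.68 and -0.73. Mesenchymal transition regulators (13) had a median of -0.05 (camera adjusted p = 0.705), and 0.14 without fresh 1, where camera's direction was upward (0.756), with VIM at -0.05 (SE 0.41), S100A4 at 1.36 (SE 0.93) and TGFBI at -1.41 (SE 0.76). No member of these lists passed, over all genes or adjusted over the list alone.

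Within the strictly named stromal-like class, ID1, ITGA11, OXTR, GAS6, MGAT5 and CCL2 differed in the same direction as over all cells. The class is part of the same counts, so the shared direction is not separate evidence. It held 47830496 of 51918079 UMIs in fresh 1 and 22902936 of 24585001 in expanded 2. In fresh 4, expanded 3 and expanded 5 it held a smaller part. ID1 stood at 243 and 190 CPM in fresh and 40.0, 44.1 and 38.2 in expanded class cells (log2 -2.34, SE 0.36), and ITGA11 at 12.6 and 13.4 against 190, 90.9 and 43.3 (log2 3.26, SE 0.87). OXTR, GAS6, MGAT5 and CCL2 had log2 folds of 3.18 (SE 0.66), 2.77 (SE 0.84), 1.75 (SE 0.51) and 3.91 (SE 1.17). Mitotic genes did not separate the groups here, with log2 folds of -0.05 (SE 1.39) for TOP2A and -0.23 (SE 1.39) for CENPF. Different clusters held the class in each library: the cluster led by CENPF and TOP2A held 99.1% of it in fresh 4, 10.8% in expanded 3 and 52.3% in expanded 5. The clusters led by HGF and by KRT81 held 42.3% and 31.6% in fresh 1, those led by PTX3 and by PLCB4 68.0% and 31.6% in expanded 2, and those led by ACTC1 and by CHI3L1 40.3% and 32.0% in expanded 3. These genes were chosen after their values were seen. The edgeR test called 0 of 16454 genes (394 at an unadjusted p under 0.05), DESeq2 called 57 (41 higher, 16 lower), and edgeR without the low-count filter called 1. At this spread edgeR recovered 0% of simulated changes of log2 1, 2 or 3.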

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

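The leave-one-out settings of the class and CDX2 shares, the settings with thinned cells, without cycling cells, with cells of stromal-marker clusters alone, with high doublet scores removed or with expanded 2 left out, and the class of all stromal-marker clusters were chosen after the data were seen. No paired analysis was possible because the labels give no donor and do not link fresh with expanded libraries. Where a group was left with 1 library, that library is assumed to vary like the other group.

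The count of 0 genes by edgeR over all cells (812 at an unadjusted p under 0.05) was 0 under every other setting tried except DESeq2, which called 176. Within the class, DESeq2 called 57 genes and edgeR with no low-count filter called 1, against 0 in the other settings. The cause was not tested.

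The stromal-like share differed by -29.8 points, and from -62.3 (without fresh 4) to 2.82 (without fresh 1) with a library left out. Counting all clusters with stromal markers gave 1.45 points, since that class adds the unnamed clusters. The mean macrophage-like and cycling shares were lower in expanded than in fresh libraries in every setting. Single libraries could overlap: with at most 10% mitochondrial UMIs the macrophage-like share was 0.372% in expanded 2 and 0.344% in fresh 1. The difference in CDX2 shares was 0.466 points, from -0.310 (without fresh 4) to 1.24 (without fresh 1) with a library left out, and -0.0522 without expanded 3. It was -0.0310 over all deposited barcodes and -0.0872 with each cell thinned to 2000 UMIs. The log2 fold change of CDX2 ran from -0.937 (without expanded 3) to 2.11 (without fresh 1).

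Of 18 gene lists called by camera, 0 were called with an estimated correlation (lowest adjusted p = 0.419) and 0 by fry (lowest 0.422). With RLE scaling 18 were called, and 15 to 16 with a library left out, 19 without cycling cells, 15 with thinned cells and 12 in stromal-marker clusters alone. The mitosis, S phase and smooth muscle lists were called with each library left out. In 4 called lists camera's direction reversed with a library left out, and only the interferon-stimulated genes were then called (upward at 2.01e-06 without fresh 1, range of adjusted p over left-out libraries 3.47e-16 to 0.499). The others were not called at the reversal: immediate early genes (0.805 without fresh 1, range from 4.29e-10, downward), imprinted genes (0.9998 without fresh 1, range from 2.24e-07, downward) and syncytiotrophoblast (0.426 without expanded 2, range from 0.00832, downward).

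For the 178 named genes, 3653 of 3902 alternative values lay within 1 SE of the main log2 fold change, 227 moved further (152 with a library left out), and 22 genes were called by DESeq2. Values of opposite sign were seen 163 times in 71 genes, none with RLE scaling or DESeq2. Depth limits the rare transcripts: CDX2 rests on 240 UMIs in 231 cells.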

Other observations

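Fresh 1 made up most of more clusters than any other library. Besides the main HGF cluster, 246 cells were led by RSAD2, TNFAIP3 and IFIT1, genes induced by interferon and NF-kB signals. Another 192 cells were led by CLIC3, BST2, VTN, KRT8, ACTG2 and TNNT2, which include smooth muscle actin and a sarcomere gene, and 103 by NPPB, NDUFA4L2, FLT1 and ESAM, genes also known from pericytes and endothelium. A cluster of 111 cells, 105 of them from fresh 1, was led by HMOX1, DDIT3 and SLC3A2, genes of oxidative and amino acid stress, and 388 cells were led by CDK1, the cardiac factor GATA4 and HGF.

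Among expanded libraries, expanded 2 had 160 cells led by PLCB4 and ROBO2, and expanded 3 had 205 led by ACTC1, the cardiac actin, with CCL2 and OXTR, and 163 led by CHI3L1, G0S2, APOE and CXCL8. Another cluster was led by GRIA4, CHRM2 and NCAM2, neural receptor and adhesion genes, with 84 cells of expanded 3 and 65 of expanded 5. MMP10 led both large clusters of expanded 5, and its level was 897 CPM there against 48.9 in expanded 3 and 0.0814 in expanded 2. Cluster-leading genes follow from the clustering and are values, not tests.

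The tests of depth and of 1 fresh library for the mitosis list, and of depth and free RNA for CDX2, were chosen after the results were seen. The mitosis list was lower in the expanded libraries (median log2 -1.57), a call of camera at a preset correlation. It is lost with an estimated one (adjusted p = 0.419 at a correlation of 0.68), so the camera p-value below holds at the preset only. Among cells of at least 2000 UMIs, unequal depth did not account for the difference. With each cell thinned to 2000 UMIs the median was -1.91, with 24 of 24 genes below 0 (camera adjusted p = 1.62e-32). Thinning left out shallower cells, 290 of them in expanded 2, so the test does not cover these. The direction did not rest on fresh 4 alone: without it the median was -0.83, nearer 0 than with all libraries, with 23 of 24 genes below 0. At equal depth the cycling share of fresh 1 (5.43%) also lay above the 1.62% to 2.51% of expanded libraries. Differences between single libraries cannot be excluded as the cause, since only 1 fresh library is then left. A difference between the fresh and expanded states stays open, since the exact permutation p of the cycling shares, 0.2, is the smallest the design allows.

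Cells with a CDX2 UMI were more frequent in the fresh 1 cluster of 346 cells led by NPPB, encoding a natriuretic peptide, and by the stress genes GADD45A, CTH and DDIT3, at 8.67% (30 cells, median 12472 UMIs) against 1.54% of the other 5179 fresh 1 cells (median 7977). This cluster was picked because it had the highest CDX2 share. Its excess remained when scaled for depth, with a ratio of CDX2 CPM of 4.07 (95% interval 2.62 to 6.18). The ratio per cell was 5.70 (3.67 to 8.66). The test cannot exclude greater depth or free RNA spread alike over droplets, since both ratios use the value that picked the cluster. Their intervals also treat cells of 1 library as independent. A stress response that goes with CDX2 in every library stays open. In fresh 1 the 10% of cells with the highest share of stress genes held 35 CDX2 UMIs against 12.6 expected, a ratio of 2.78. In the other 4 libraries together such cells held 8 against 10.3 expected, a ratio of 0.778 (0.336 to 1.53), though expanded 2 alone held 3 against 1.16. No excess was seen over these 4 libraries, but so few UMIs cannot exclude a small excess. A candidate explanation, found and tested on the same data, is that CDX2 transcript may mark a state of cells in that library alone.

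Expanded 2 correlated less with expanded 3 and 5 than these did with each other. Giving its cells equal weight did not raise its correlations. With each cell thinned to 2000 UMIs the higher was 0.746 over 3280 genes (0.778 before thinning). That lay under the lowest of the pairs without it, 0.809, and under 0.892 for expanded 3 with expanded 5. The test cannot exclude its few deep cells as the cause, since thinning left out 290 of its shallower cells. Its thinned sum of 1238000 UMIs was also the lowest, against 4368000 to 10450000 in the other libraries. Correlations are across genes, which are not independent replicates. No biological explanation was tested, and a difference between donors or cultures stays open.

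As a hypothesis, cells with a CDX2 UMI might carry a trophoblast programme. In 230 such cells against 10 matched cells each, the early trophoblast list without CDX2 had a median log2 of -0.17 over 8 genes (camera adjusted p = 0.0533, and 0.404 with an estimated correlation), so the list was not higher. Camera placed 8 of 29 lists lower (lowest adjusted p = 1.08e-05), none with an estimated correlation (lowest 0.404). EdgeR called 5 of 10524 genes (865 at an unadjusted p under 0.05). SPIRE1 and IL33 were higher (log2 0.58 and 1.07), and ANKRD1, NEFL and AC097480.1 lower (-0.92, -2.61 and -2.41). On simulated counts this test recovered 60 of 64 changes of log2 1 but also called 23 unchanged genes of 10400, so these 5 calls can be false. The hypothesis stays open, because cells without a UMI can also express CDX2 and the bound set before the test asked for no other called gene.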
